A study of Arabidopsis thaliana with 12 samples.

How the data were processed

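RNA was sequenced from germinating seeds of Arabidopsis thaliana in 12 libraries, 2 biological replicates (as the labels call them) for each of 3 genotypes under each of 2 treatments. The genotypes were amiR-HsMYO, the control line of the series, and amiR-SYD-1 and amiR-SYD-2, which carry artificial microRNAs directed against SPLAYED (SYD). They are called HsMYO, SYD1 and SYD2 here. Seeds were kept at 4 °C in the dark for 3 days and then treated for 24 h, in a 16 h light and 8 h dark cycle, with 2 µM (±)-abscisic acid (ABA) or with 0.002% ethanol. Libraries were made with a stranded mRNA kit and sequenced as 100 bp pairs.

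The deposited table holds raw counts per gene, 1 column per library. By the submitters' processing notes, reads were trimmed with Trimmomatic 0.39 and aligned with STAR 2.7.10a to the TAIR10 genome. The counting program, its strand setting, its treatment of reads that map to several places and the annotation version are not given in the sources used here. Counts of overlapping or antisense genes, and the split of counts among near-identical copies such as the SESA, RBCS, LHCB1, KIN and extensin genes, therefore carry an error that was not measured. The table had 36795 entries, of which 36632 matched a locus tag of the TAIR10.1 reference annotation and 10729 had 0 counts in every library. Every one of its 12 count columns was used. Gene positions are those of the reference annotation and names are its symbols; where it gives no symbol, the name in the fixed gene lists was used.

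Total counts per library ran from 18713555 to 30012796. A count of 3 corresponded to 0.101 to 0.162 CPM per library, CPM being the usual count scaled to library size. Where a group had 0 counts in both libraries, a fold is given as a lower bound against a floor of 3 counts over the group; with 1 to 3 counts over a group, the ratio is given with its exact 95% binomial (Clopper-Pearson) interval, scaled by effective library sizes. These floors and intervals cover counting error only, since PCR duplicates cannot be told from separate molecules in a count table. Across genes with at least 20 counts, the replicate chi-square divided by its degrees of freedom lay between 2.4 and 13.37 in the 6 groups, so replicates differed by more than counting error.

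Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 19612 tested genes. Libraries were scaled by TMM factors, and a quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries, leaving 6 residual degrees of freedom (prior 9.2; common biological coefficient of variation 6.3%). Contrasts were tested 2-sided with the quasi-likelihood F-test, and p-values were adjusted by Benjamini-Hochberg over the tested genes of each contrast. A gene was called at an adjusted p under 0.05. CPM values are means of 2 libraries on the TMM scale with their SD; log2 fold changes carry the standard error (SE) of the model. Replicate 1 and replicate 2 were not treated as pairs, because the labels state no pairing; residual correlations between groups with the same replicate number ran from -0.03 to 0.15, with a median of 0.07.

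The contrasts were ABA against ethanol in each line; each SYD line, and the mean of both, against HsMYO in each treatment; the difference between the ABA response of each SYD line, or of their mean, and that of HsMYO; and SYD1 against SYD2 in each treatment. The comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Both SYD lines share the same 2 HsMYO libraries as the control in each treatment, which makes their changes alike by construction. The number of genes shared by both lines was therefore set beside 20 simulated draws in which counts had the fitted means of HsMYO and the fitted dispersions and the control was shared.

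The 21 lists, with 312 genes, were ABA and dehydration effector genes; ABA receptors; ABA-linked transcription factors and AFPs; clade A PP2C phosphatases; LEA and late seed maturation genes; seed storage and oil body proteins; reserve mobilisation; gibberellin metabolism and signalling; cell wall loosening and cell expansion; photosynthesis and chlorophyll synthesis; cell cycle and DNA replication; ribosomal proteins and ribosome biogenesis; SWI/SNF remodeler subunits; Polycomb repression; jasmonate, ethylene and defence markers; heat shock proteins; auxin response and transport; and markers of the root epidermis and root tip, of the shoot meristem and boundary, of the seed coat and of the endosperm. Members were matched by AGI identifier. RPL8A and SWP73B were dropped because the reference names their identifiers otherwise, 5 members without a name in the reference were kept, and 275 members were tested. Lists were tested against all other genes with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with the correlation estimated from the residuals; p-values were adjusted over the 21 lists.

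Genes are named by a fixed rule in 4 comparisons: SYD; a panel of ABI3, ABI4, ABI5, EM1, EM6, RAB18 and RD29B; up to 2 called members with the smallest adjusted p from each list; and up to 4 called genes with a symbol and the largest change in each direction among those with at least 5 CPM in a group compared and no overlap between libraries of the groups. For comparisons with HsMYO the change had to have the same sign in both SYD lines, and organelle genes were left out. For the difference between responses, that shared sign took the place of the rule on overlap between libraries. Genes named outside the rule are said to be chosen after their values were seen.

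The gene and list tests were run on simulated data with the depths and dispersions of these libraries over 19238 genes. Changes were planted only in HsMYO on ABA and only in genes with a mean of at least 1 CPM. Recovery at lower counts, and scaling when many genes change, were therefore not tested. For the ABA contrast in HsMYO, 71.6% of planted 1.5-fold changes, 88.1% of 2-fold changes and 100% of 4-fold changes were called, with 14 false among 187 calls. For the difference between responses the shares were 59.7%, 82.1% and 100%, with 15 false among 176 calls. Camera called the 1 raised list and 0 of 50 random lists with either correlation. Simulated genes varied independently of each other, so this cannot show whether the preset correlation is safe for lists whose members vary together. For ABA in HsMYO, the estimated correlation was 0.703 for photosynthesis, 0.715 for storage, 0.436 for LEA and 0.236 for cell cycle genes. It was 0.012 for ABA-linked transcription factors and -0.061 for auxin genes. Where it lay far above 0.01, the p-values at the preset correlation are likely too small.

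The alternatives were RLE scaling, no low-count filter, a stricter filter of 5 CPM in at least 2 libraries, replicate number as a block, a fit to only the groups compared, DESeq2 1.42.0, calls that also need a 2-fold change, calls at an adjusted p under 0.01, an estimated correlation for the lists, and leaving out each of the 12 libraries in turn. A group left with 1 library is assumed to vary like the other groups.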

Results

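Polyadenylated RNA was sequenced from germinating Arabidopsis seeds of 3 lines, each given the growth-arresting hormone ABA (2 µM) or ethanol for 24 h. HsMYO was the control line, and SYD1 and SYD2 carried artificial microRNAs against SYD, the gene of a SWI/SNF chromatin-remodelling ATPase. Each of the 6 groups had 2 libraries. Total counts (replicates 1 and 2) were 22648488 and 24613812 for HsMYO without ABA, and 30012796 and 25486979 for HsMYO on ABA. They were 18713555 and 18870568 for SYD1 without ABA, and 19736632 and 21776076 on ABA. SYD2 had 21118621 and 27606120 without ABA, and 23121495 and 22111190 on ABA. The isocitrate lyase gene ICL was the most counted gene in every library, with 1.69 to 2.83% of its counts. The series asks, in short, whether SYD is needed for ABA to halt growth after germination.

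SYD transcript (AT2G28290, TAIR10.1 chromosome 2, 12056213 to 12073279), the target of the microRNAs, was lower in both SYD lines under both treatments, though far from absent. BRM, which encodes the closest related ATPase and has no microRNA against it here, did not differ detectably, whereas CHR23, for another ATPase of the family, was lower. Without ABA, SYD stood at 182 ± 4.66 CPM (SD, n = 2) in HsMYO, 105 ± 5.17 in SYD1 and 103 ± 6.39 in SYD2. On ABA it stood at 213 ± 23.7, 149 ± 6.02 and 136 ± 14.9 CPM. The mean of the SYD lines was 1.75-fold lower than HsMYO without ABA (log2 -0.81 ± 0.08 SE, adjusted p = 1.4e-06) and 1.5-fold lower on ABA (-0.58 ± 0.08, adjusted p = 3.7e-05), with all SYD line libraries below all HsMYO libraries of the same treatment. SYD itself rose on ABA by 0.51 (adjusted p = 0.00029) in SYD1 and 0.4 (adjusted p = 0.0022) in SYD2. Its rise in HsMYO was at the edge of the threshold (0.23, adjusted p = 0.04; 0.2 with DESeq2, adjusted p = 0.075, and 0.2 with RLE scaling, adjusted p = 0.066), and the difference between the responses was not called (0.23, adjusted p = 0.28). The call in HsMYO ended without HsMYO on ABA replicate 2 (0.1), without HsMYO without ABA replicate 1 (0.25) or 2 (0.2), without SYD1 on ABA replicate 1 (0.2) or 2 (0.23), without SYD1 without ABA replicate 1 or 2 (0.23 each), and without SYD2 without ABA replicate 1 (0.2). BRM, named after its values were seen, differed by -0.02 (adjusted p = 0.88) without ABA and 0.08 (adjusted p = 0.32) on ABA. CHR23 was lower by -0.36 (adjusted p = 0.0014) and -0.65 (adjusted p = 6.3e-06). Counts of the transcript do not show how much SYD protein was left.

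**Figure D1:**
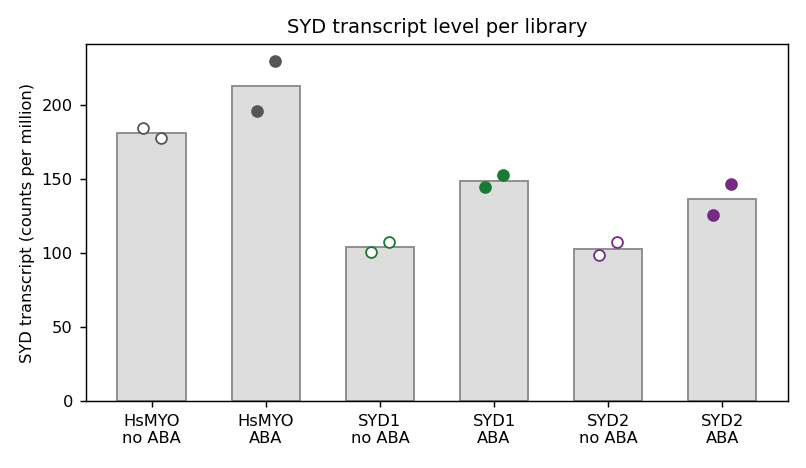
SYD transcript level (CPM) in each line with ethanol or ABA; bars are means of 2 libraries and points are single libraries. The SYD line libraries lie below the HsMYO libraries of the same treatment, with group means of 103 to 149 against 182 and 213 CPM.

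ABA separated the libraries along the first principal component of log CPM values, which held 69.8% of the variance. Ethanol libraries lay between 50.1 and 77.2 on it and ABA libraries between -78.5 and -52.9. The second component, with 15.5%, separated HsMYO (37 to 50.4) from both SYD lines (-28.5 to -15.4). The fourth component (2.8%) ordered the replicates the same way in 5 of 6 groups and the fifth (1.6%) in 6 of 6. In addition, 392 genes were called for replicate number when it was fitted as a block. Libraries with the same replicate number thus shared some variation, which the main fit left in its spread.

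**Figure D2:**
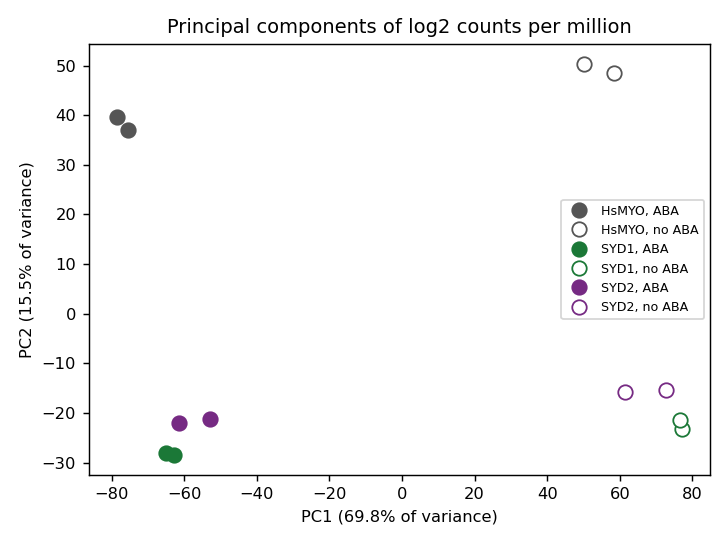
The first 2 principal components of log CPM values of the tested genes (69.8% and 15.5% of the variance), with 1 point per library. ABA and ethanol libraries part along the first, and HsMYO and SYD line libraries along the second.

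The response of the control line to ABA answers what the hormone did to seeds with normal SYD. ABI5, for a bZIP factor that holds back growth, rose, and so did its targets EM1 and EM6, which encode late embryogenesis abundant (LEA) proteins. The clade A PP2C phosphatase genes AHG1 and HAI3, which damp ABA signalling, rose too, whereas the receptor gene PYL6 fell. PORB for chlorophyll synthesis, the vacuolar water channel gene TIP1;1 and the root-hair genes EXT10 and COBL9 went down. ABA changed 10594 of 19612 genes (5272 higher, 5322 lower), 2977 of them at least 2-fold.

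ABI5 (AT2G36270, chromosome 2, 15204659 to 15207636) went from 28.9 ± 4.07 to 209 ± 2.51 CPM (SD, n = 2), 7.26-fold higher (log2 2.86 ± 0.09 SE, adjusted p = 1.5e-12). EM1 (AT3G51810, chromosome 3, 19214722 to 19215831) rose 61-fold, from 11 ± 6.72 to 664 ± 87.4 CPM (5.93 ± 0.28, adjusted p = 1e-10). EM6 (AT2G40170, chromosome 2, 16779552 to 16780368) rose 77.1-fold, from 6.04 ± 3.81 to 458 ± 24.9 CPM (6.27 ± 0.27, adjusted p = 3.2e-11). The dehydration genes RD29A, KIN1, TSPO, RD29B and RAB18, which respond to ABA in vegetative tissue as well, rose by 7.09, 7.07, 6.57, 5.87 and 5.34 on the log2 scale. The seed regulators ABI3 and SOM rose by 0.92 and 3.42, and the DELLA gene RGL2, which restrains gibberellin-driven germination, by 1.4 (adjusted p = 3.5e-10). ABI4 rose by only 0.25 (adjusted p = 0.016). The phosphatase genes AHG1 and HAI3 rose by 4.61 and 4.04, while the receptor gene PYL6 was 10.1-fold lower (-3.34, adjusted p = 3.3e-12). PORB (AT4G27440) was 19.5-fold lower, at 25.2 ± 8.6 against 494 ± 6.35 CPM, and TIP1;1 (AT2G36830, chromosome 2, 15445294 to 15446621) was 89.7-fold lower, at 0.635 ± 0.043 against 57.3 ± 3.19 CPM (log2 -6.49 ± 0.2 SE, adjusted p = 1.1e-12).

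Among cell wall genes of root hairs, the extensin gene EXT10 had 301 counts without ABA and 0 on ABA, at least 119-fold lower. COBL9, needed for root hair growth, had 106 counts and 1, a ratio of 125 (95% interval 22 to 4990). The amino acid transporter gene UMAMIT17 had 1125 counts and 1, a ratio of 1330 (238 to 52600). The auxin-conjugating enzyme gene GH3.3 fell by 4.26 and the jasmonate repressor gene JAZ1 by 1.31 on the log2 scale. The call for ABI4 ended without HsMYO on ABA replicate 2 (0.17, adjusted p = 0.13) or HsMYO without ABA replicate 2 (0.15, adjusted p = 0.22), and with only the groups compared (0.24, adjusted p = 0.077).

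As lists, LEA and late seed maturation genes (11 of 12 higher, 0 lower, adjusted p = 1.2e-18; adjusted p = 0.037 with an estimated correlation), clade A PP2C phosphatases (8 of 9 higher, 1 lower, adjusted p = 2.4e-14; adjusted p = 0.023 with an estimated correlation) and effector genes (11 of 15 higher, 4 lower, adjusted p = 1.2e-12; adjusted p = 0.023 with an estimated correlation) rose. ABA-linked transcription factors rose (13 of 19 higher, 4 lower, adjusted p = 1e-05; adjusted p = 0.026 with an estimated correlation), and so did seed storage and oil body genes (6 of 14 higher, 0 lower, adjusted p = 0.0015; adjusted p = 0.61 with an estimated correlation). Photosynthesis genes fell (29 of 31 lower, 1 higher, adjusted p = 7.3e-16; adjusted p = 0.27 with an estimated correlation), as did ABA receptors (7 of 9 lower, 1 higher, adjusted p = 8.2e-07; adjusted p = 0.081 with an estimated correlation). Cell cycle and DNA replication genes fell (18 of 24 lower, 2 higher, adjusted p = 0.036; adjusted p = 0.61 with an estimated correlation), and auxin genes fell (9 of 11 lower, 2 higher, adjusted p = 0.036; adjusted p = 0.15 with an estimated correlation). Adjusted over the list alone, these counts were the same except for the transcription factors, with 5 lower. The number of called lists was 7 without HsMYO on ABA replicate 2, and 8 without HsMYO on ABA replicate 1 or HsMYO without ABA replicate 1.

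The other 12 lists were not called. Cell wall loosening genes split (6 higher, 6 lower of 16, adjusted p = 0.35), with a median of 0.05 but a mean of -0.54 and a test pointing down. Gibberellin genes had 9 higher and 5 lower of 18 (adjusted p = 0.55), reserve mobilisation 3 and 6 of 17 (adjusted p = 0.57), ribosome genes 2 and 3 of 19 (adjusted p = 0.81) and root markers 1 and 6 of 13 (adjusted p = 0.45). SWI/SNF subunits had 5 higher and 1 lower of 13 (adjusted p = 0.47), Polycomb genes 2 and 5 of 8 (adjusted p = 0.81), heat shock proteins 0 and 4 of 8 (adjusted p = 0.38), and jasmonate, ethylene and defence markers 1 and 2 of 6 (adjusted p = 0.55). Shoot meristem markers had 1 higher and 2 lower of 7 (adjusted p = 0.81), seed coat markers 0 and 2 of 3 (adjusted p = 0.2) and endosperm markers 1 and 0 of 3 (adjusted p = 0.81). Adjusted over the list alone, the counts changed for gibberellin genes (10 higher), heat shock proteins (5 lower), endosperm markers (1 lower) and shoot meristem markers (0 higher, 1 lower).

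The SYD lines show whether ABA still acts when SYD is reduced. ABI5, EM1 and RD29B rose steeply in both SYD lines, and PORB, which serves the greening seedling, fell in both (-3.73 and -3.68). ABI5 rose by 3.03 in SYD1 and 3.02 in SYD2 (log2; 2.86 in HsMYO), with no called difference (mean 0.16, adjusted p = 0.46). EM1 rose by 6.81 and 6.2 (mean difference 0.57, adjusted p = 0.41), RD29B by 6.68 and 5.7 (0.32, adjusted p = 0.56), RAB18 by 4.71 and 4.55 (-0.71, adjusted p = 0.44) and EM6 by 4.81 and 5.46 (-1.13, adjusted p = 0.15). The replicates of HsMYO without ABA lay far apart for these 4 genes (14.5 ± 11 CPM for RAB18): without replicate 1 of that group the differences were -0.22 for EM1, -0.17 for RD29B, -1.8 for RAB18 (adjusted p = 0.048) and -1.95 for EM6 (adjusted p = 0.0083), and without replicate 2 EM1 differed by 1.11 (adjusted p = 0.023). The difference for EM6 was called with replicate number as a block (-1.18, adjusted p = 0.017). With no low-count filter those for EM6 (-1.1, adjusted p = 8.9e-09), EM1 (0.61, adjusted p = 0.00016), RAB18 (-0.68, adjusted p = 2.6e-07) and RD29B (0.36, adjusted p = 0.05) were called. The sizes hardly moved from the main fit, so the calls came from the fitted spread. The 2 HsMYO libraries without ABA read 22.3 and 6.73 CPM for RAB18, a spread that such p-values do not reflect. ABA changed 9195 genes in SYD1 (4262 higher, 4933 lower) and 8417 in SYD2 (3798 higher, 4619 lower). The same direction was called in all 3 lines for 6394 genes (2868 higher, 3526 lower), and 63 were called in opposite directions in HsMYO and a SYD line. Across genes, which are not independent replicates, log2 ABA responses correlated between HsMYO and each SYD line at r = 0.87, and between the SYD lines at 0.93.

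The LEA list rose in SYD1 (11 of 12 higher, adjusted p = 2.7e-23; adjusted p = 0.036 with an estimated correlation) and SYD2 (10 of 12 higher, adjusted p = 1.3e-22; adjusted p = 0.032 with an estimated correlation). Clade A PP2C phosphatases, effector genes, ABA-linked transcription factors, receptors, photosynthesis and storage genes were called in both SYD lines in the same direction as in HsMYO. In SYD1 and SYD2, photosynthesis had an adjusted p = 0.12 with an estimated correlation and an adjusted p = 0.26 with an estimated correlation. Storage had 0.33 and 0.49, and receptors 0.073 and 0.032. The phosphatase, effector and factor lists each had an adjusted p = 0.016 with an estimated correlation in SYD1 and an adjusted p = 0.023 with an estimated correlation in SYD2. The cell cycle list was called in HsMYO (adjusted p = 0.036; adjusted p = 0.61 with an estimated correlation) but not in SYD1 (3 higher, 9 lower of 24, adjusted p = 0.66) or SYD2 (2 higher, 9 lower, adjusted p = 0.68). The median size of the ABA response, over genes chosen in the line left over, differed by -0.02 (SD 0.015 over 16 choices of libraries) for SYD1 minus HsMYO, -0.078 (SD 0.034) for SYD2 minus HsMYO and -0.051 (SD 0.03) for SYD2 minus SYD1. Over genes that also changed 2-fold, these values were 0.031, with the sign reversed, -0.155 and -0.156. For SYD1 the value was -0.002 without HsMYO on ABA replicate 2 and -0.004 without SYD2 without ABA replicate 1, and for SYD2 minus SYD1 it was -0.021 without SYD2 without ABA replicate 2.

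**Figure D3:**
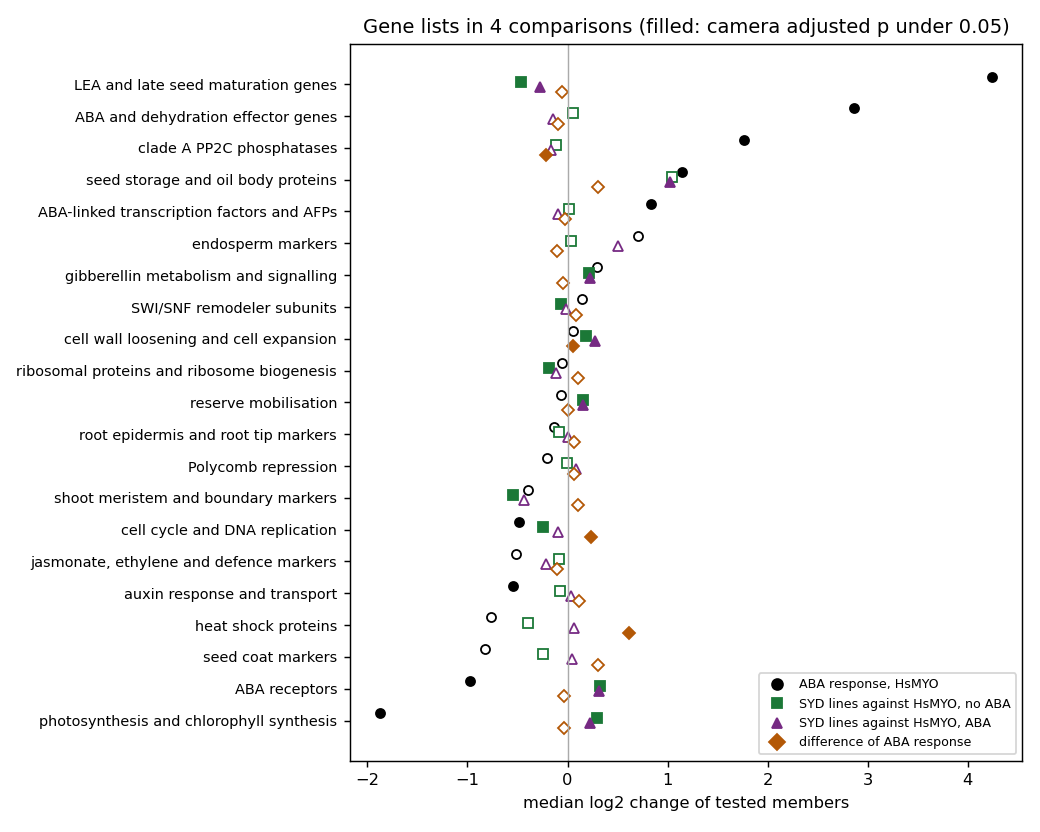
Median log2 change of the tested members of the 21 gene lists in 4 comparisons; filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation. On ABA in HsMYO, LEA genes and PP2C phosphatases rise and photosynthesis genes fall (adjusted p = 0.27 with an estimated correlation), and the difference of responses is called for 4 lists (each at adjusted p = 0.56 with an estimated correlation).

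The difference between the ABA response of the SYD lines and that of HsMYO shows which responses differed between the lines. With 1 control line it cannot show which of them need SYD. A gene that differed between the lines only without ABA is called here as well. GA3OX1 and GA3OX2 encode the enzymes that make active gibberellin, the hormone that drives germination, and ABA lowered them less in the SYD lines. TIP1;1, a marker of expanding cells, also fell less, whereas the expansin gene EXPA1 fell only in the SYD lines. The phosphatase genes HAI2 and ABI1 and the maturation factor gene ABI3 responded differently too, from levels that already differed between the lines without ABA. The mean response differed for 1008 genes (527 with a higher and 481 with a lower response in the SYD lines), 290 of them by at least 2-fold.

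GA3OX1 (AT1G15550, chromosome 1, 5344388 to 5346342) fell from 21.6 ± 2.72 to 4.43 ± 0.298 CPM (SD, n = 2) in HsMYO, from 15.7 ± 1.21 to 8.62 ± 0.101 in SYD1 and from 16.1 ± 1.9 to 9.13 ± 1.36 in SYD2. These were decreases of 4.86-fold, 1.82-fold and 1.77-fold, and the responses differed by 1.44 ± 0.17 SE (log2, adjusted p = 0.00017). GA3OX2 (AT1G80340, chromosome 1, 30200466 to 30202349) was 2.38-fold lower on ABA in HsMYO, at 52.5 ± 4.46 against 125 ± 6.35 CPM, but 1.25-fold and 1.23-fold lower in SYD1 and SYD2 (difference 0.94 ± 0.09, adjusted p = 3e-05). TIP1;1 was 89.7-fold lower on ABA in HsMYO, 19-fold lower in SYD1 and 12.1-fold lower in SYD2 (difference 2.56 ± 0.3, adjusted p = 0.00018). EXPA1 (AT1G69530) was not called for ABA in HsMYO (-0.13, adjusted p = 0.13) and fell in SYD1 (-0.82) and SYD2 (-0.95), a difference of -0.75 ± 0.09 (adjusted p = 0.00018).

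HAI2 rose less in the SYD lines (2.34 and 2.48, against 3.69 in HsMYO; difference -1.28, adjusted p = 0.00017) and ABI1 fell more (-1.38 and -1.43, against -0.7; difference -0.71, adjusted p = 0.0054). ABI3 rose more (1.64 and 1.51, against 0.92; difference 0.65, adjusted p = 0.0032), from a lower level without ABA, while ABI4 did not differ detectably (0.15, adjusted p = 0.44). The LEA gene ECP63 also rose more (1.37, adjusted p = 0.0071), from a lower level without ABA (-2.17, adjusted p = 7.5e-07). Without HsMYO without ABA replicate 1, its difference was 0.8. P5CS1, for proline synthesis under stress, fell less (0.93, adjusted p = 0.00079), and ADH1, for alcohol dehydrogenase, rose in HsMYO (1.69) but was not called in SYD1 or SYD2 (difference -1.39, adjusted p = 0.0021). The wax alkane hydroxylase gene CYP96A15 went from 160 counts to 1 in HsMYO, a ratio of 189 (95% interval 33.5 to 7520), and fell by 2.74 and 2.53 on the log2 scale in SYD1 and SYD2. STS, for stachyose synthesis, rose by 4.81 in HsMYO against 0.37 (not called) and 1.1 in the SYD lines, and the receptor kinase gene IOS1 fell by 1.09 in HsMYO against 4.56 and 3.48.

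Cell cycle genes responded higher, that is fell less (3 of 24 called higher, 0 lower, or 9 and 0 adjusted over the list alone, with adjusted p = 3.6e-05 and adjusted p = 0.56 with an estimated correlation). They started from a lower level in the SYD lines without ABA (median -0.25, 0 higher, 11 lower). On ABA the list was not called against HsMYO (median -0.1, 6 higher, 11 lower). Cell wall loosening genes (4 higher, 1 lower of 16, or 7 and 1 adjusted over the list alone; adjusted p = 0.031; adjusted p = 0.56 with an estimated correlation) and heat shock proteins (2 higher, 0 lower of 8, the same adjusted over the list alone; adjusted p = 0.031; adjusted p = 0.56 with an estimated correlation) also responded higher. Clade A PP2C phosphatases responded lower (0 higher, 3 lower of 9, the same adjusted over the list alone; adjusted p = 0.002; adjusted p = 0.56 with an estimated correlation). The gene count was 540 without HsMYO without ABA replicate 1 and 1584 without HsMYO on ABA replicate 1, and it was 1817 with no low-count filter and 1628 with replicate number as a block. The number of called lists was 2 without SYD2 without ABA replicate 1 and 7 without HsMYO without ABA replicate 2.

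The SYD lines were also set against HsMYO in seeds on ABA, a hormone that holds growth back. The counts give no measure of growth. EM6, a marker of the arrested, desiccation-tolerant state, was much lower in the SYD lines on ABA, and KIN1 and ABI5 were lower as well. The gibberellin-induced gene GASA4, GA3OX1, GA3OX2, the expansin gene EXPA8 and the greening genes GLK2 and PORB were higher. Storage albumin genes SESA2 and SESA4 and the reserve-mobilising gene ICL were higher too. The mean of the SYD lines differed from HsMYO for 6401 genes (3290 higher, 3111 lower), 1216 of them at least 2-fold. DESeq2 called 4595, with 2866 higher and 1729 lower, and RLE scaling gave 3682 higher and 2689 lower, so the split depends on scaling. Of the 6401 genes, 3455 (54%) were called in the same direction without ABA and 107 in the opposite direction. Many of the differences were therefore not particular to seeds on ABA.

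EM6 stood at 458 ± 24.9 CPM (SD, n = 2) in HsMYO, 58 ± 13.7 in SYD1 and 59.3 ± 10.8 in SYD2, 7.82-fold lower (log2 -2.97 ± 0.17 SE, adjusted p = 7.4e-09). KIN1 (AT5G15960, chromosome 5, 5209717 to 5210826) stood at 23 ± 4.02, 4.85 ± 0.947 and 5.1 ± 1.02 CPM, 4.63-fold lower (-2.21 ± 0.14, adjusted p = 2.2e-08). ABI5 stood at 209 ± 2.51, 164 ± 1.68 and 163 ± 8.43 CPM (-0.36 ± 0.07, adjusted p = 0.0012), and EM1 at 664 ± 87.4, 389 ± 41.5 and 353 ± 9.31 CPM (-0.84 ± 0.18, adjusted p = 0.0025; -0.82 with DESeq2, adjusted p = 0.16). ABI3 (0.13, adjusted p = 0.24), ABI4 (0.16, adjusted p = 0.091), RAB18 (-0.31, adjusted p = 0.44) and RD29B (-0.29, adjusted p = 0.15) were not called. Without HsMYO on ABA replicate 2, ABI4 was called (0.24, adjusted p = 0.047), and without HsMYO on ABA replicate 1, RAB18 was at 0.05. RD29B was called with replicate number as a block (-0.29, adjusted p = 0.048), with only the groups compared (adjusted p = 0.015) and with no low-count filter (adjusted p = 0.00033), and RAB18 with no low-count filter (-0.3, adjusted p = 0.00014). The sizes hardly moved from the main fit, so these calls came from the fitted spread. Of the PP2C phosphatase genes, ABI2 (-0.85) and AHG1 (-0.54) were lower, while the receptor gene PYL6 was 2.02-fold higher (1.01, adjusted p = 1.5e-05).

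GASA4 (AT5G15230, chromosome 5, 4944816 to 4946299) stood at 198 ± 1.23 CPM in HsMYO, 669 ± 60.1 in SYD1 and 644 ± 73 in SYD2, 3.32-fold higher (1.73 ± 0.09, adjusted p = 4.6e-09). GA3OX2 was higher by 0.86 (adjusted p = 1.4e-07) and GA3OX1, named here after its values were seen, by 1 (adjusted p = 4.1e-05). EXPA8 (AT2G40610, chromosome 2, 16948791 to 16950705) stood at 62.5 ± 4.54, 177 ± 4.66 and 184 ± 9.16 CPM, 2.89-fold higher (1.53 ± 0.07, adjusted p = 4.6e-10), and EXPA9 was higher by 1.03. GLK2, for a transcription factor of chloroplast development, was 2.09-fold higher (1.06, adjusted p = 2.3e-08) and PORB 2.89-fold higher (1.53, adjusted p = 5.1e-06). SESA2 was 3.93-fold higher (1.97, adjusted p = 1.9e-06), SESA4 was 7.21-fold higher (2.85, adjusted p = 5e-06) and ICL 1.56-fold higher (0.64, adjusted p = 7.4e-05). The DNA replication gene MCM6 (-0.56) and the cyclin gene CYCD1;1 (-0.71) were lower, whereas the mitotic genes CDKB2;2, KN and AUR1, chosen after their values were seen, were higher (0.95, 0.76 and 0.73). The cell cycle list, with 6 higher and 11 lower of 24, was not called (adjusted p = 0.36). The beta-amylase gene BAM5 was 12.6-fold higher (3.66, adjusted p = 1e-07), the lipid transfer protein gene LTP3 was 12.4-fold lower (-3.64, adjusted p = 1.9e-12) and the proteinase inhibitor gene UPI was 27-fold lower (-4.75, adjusted p = 4.5e-10). PR1, a defence marker, had 1 count in HsMYO against 68 in SYD1, a ratio of 93.5 (95% interval 16.2 to 3750), and 35 in SYD2, a ratio of 44.6 (7.5 to 1810).

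Cell wall loosening genes were higher as a list (9 of 16 higher, 1 lower, the same adjusted over the list alone; adjusted p = 0.00019; adjusted p = 0.28 with an estimated correlation), and so were gibberellin genes (8 of 18 higher, 3 lower, or 9 and 3 adjusted over the list alone; adjusted p = 0.0019; adjusted p = 0.14 with an estimated correlation). Photosynthesis (11 higher, 0 lower of 31), reserve mobilisation (6 and 0 of 17), storage (7 and 3 of 14) and receptor genes (6 and 0 of 9) were higher and LEA genes lower (2 higher, 6 lower of 12). These 5 lists had an adjusted p of 0.024, or 0.032 for the receptors; with an estimated correlation, adjusted p = 0.72 for photosynthesis and storage and adjusted p = 0.69 with an estimated correlation for the other 3. Adjusted over the list alone, photosynthesis had 1 lower and reserve mobilisation 7 higher. The number of called lists was 4 without HsMYO on ABA replicate 1 and without SYD2 on ABA replicate 2, and 5 without HsMYO on ABA replicate 2.

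**Figure D4:**
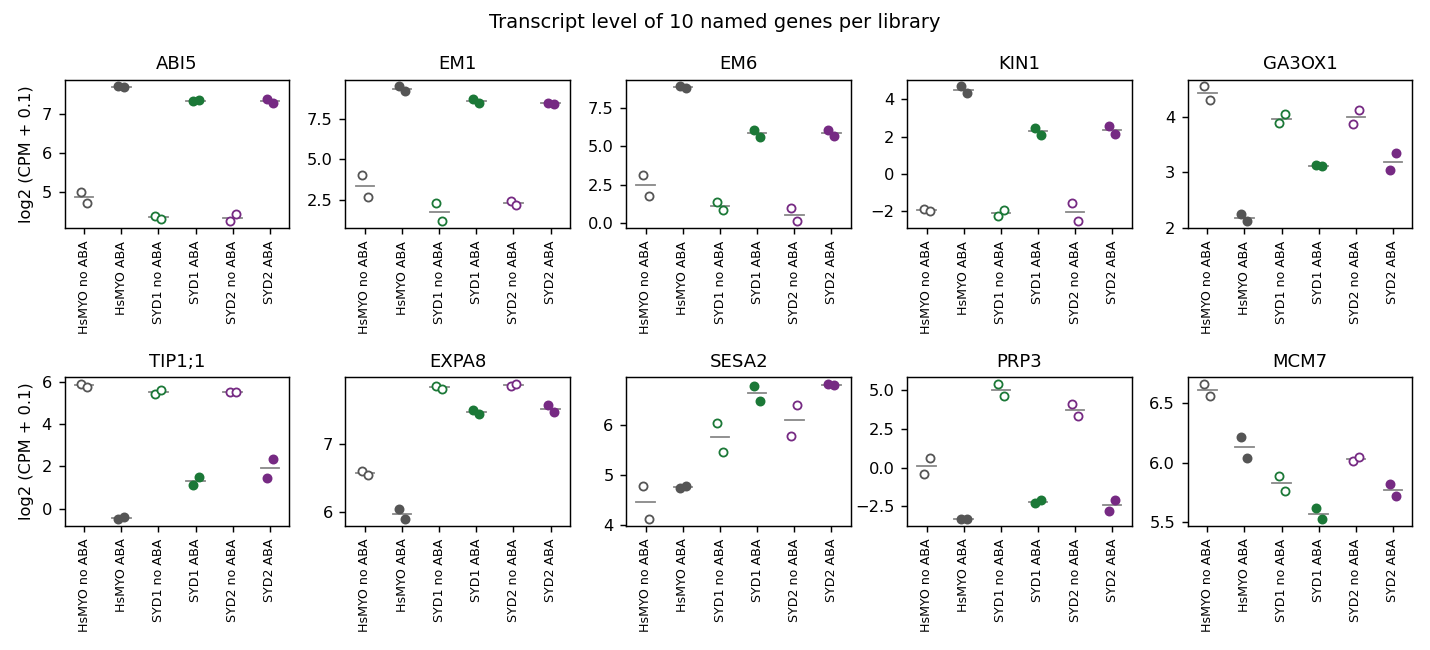
Expression of 10 genes, as log2 (CPM + 0.1), in each line with ethanol or ABA; points are single libraries and lines are means of 2 libraries. On ABA, EM6 and KIN1 lie lower, and GA3OX1, TIP1;1, EXPA8 and SESA2 higher, in the SYD lines than in HsMYO.

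Seeds without ABA show how the lines differed with no hormone added. MCM7 and MCM4, genes of the helicase that opens DNA for replication, were lower in the SYD lines, and so were the maturation genes LEA4-5, ECP63 and ABI3. Higher were the expansin genes EXPA8 and EXPA9, the greening genes GLK2 and PORA, the gibberellin genes GA20OX2 and GASA6, the root-hair gene PRP3 and the phosphatase genes ABI1 and HAI2. The mean of the SYD lines differed for 6311 genes (3476 higher, 2835 lower), 1199 of them at least 2-fold. Without HsMYO without ABA replicate 1, 3455 genes were called, and with no low-count filter 6834 were (3287 higher, 3547 lower).

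MCM7 (AT4G02060, chromosome 4, 900636 to 905591) stood at 97.8 ± 4.57 CPM (SD, n = 2) in HsMYO, 56.7 ± 3.54 in SYD1 and 65.3 ± 1.11 in SYD2, 1.61-fold lower (log2 -0.68 ± 0.06 SE, adjusted p = 1.1e-06), and MCM4 was lower by a similar size (-0.62, adjusted p = 1.6e-06). LEA4-5 was 2.8-fold lower (-1.48, adjusted p = 5.7e-07), ECP63 was 4.5-fold lower (-2.17, adjusted p = 7.5e-07), ABI3 lower (-0.52, adjusted p = 0.00016) and ABI5 lower (-0.52, adjusted p = 0.00022). EM1 (-1.42, adjusted p = 0.0017), EM6 (-1.84, adjusted p = 0.0012) and RD29B (-0.61, adjusted p = 0.037) were lower, but without HsMYO without ABA replicate 1 none of the 3 was called (-0.62, -1.01 and -0.12), and ABI3 was at -0.34. RD29B was also not called without SYD1 without ABA replicate 1 (-0.52) or SYD2 without ABA replicate 2 (-0.45), with DESeq2 (-0.61, adjusted p = 0.13) or with only the groups compared (-0.63, adjusted p = 0.056), and stood at -1 without HsMYO without ABA replicate 2. ABI4 (0.01, adjusted p = 0.95) and RAB18 (0.4, adjusted p = 0.44) were not called, though RAB18 was called at 1.49 without HsMYO without ABA replicate 1 and stood at -0.23 without replicate 2. With no low-count filter RAB18 was called at 0.37 (adjusted p = 0.00028), a size close to the main fit, so this call came from the fitted spread.

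EXPA8 stood at 95.1 ± 2.98 CPM in HsMYO, 228 ± 5.09 in SYD1 and 234 ± 2.75 in SYD2, 2.43-fold higher (1.28 ± 0.06, adjusted p = 2.4e-09). GLK2 was 2.29-fold higher (1.2, adjusted p = 5.5e-09), GA20OX2, for a gibberellin oxidase, was 2.89-fold higher (1.53, adjusted p = 2.3e-06), and PORA and GASA6 were higher by 2.04 and 1.02. ABI1 (AT4G26080, chromosome 4, 13219915 to 13222376) stood at 89 ± 15.8, 226 ± 4.98 and 214 ± 12 CPM, 2.47-fold higher (1.3 ± 0.1, adjusted p = 1.3e-07), and HAI2 was 2.47-fold higher as well. PRP3 stood at 1.06 ± 0.562, 32.7 ± 12.3 and 13.6 ± 5.24 CPM (4.27, adjusted p = 4.5e-07). SESA4 and SESA2 were 5.61-fold and 2.79-fold higher. ARD3, for a methionine salvage enzyme, had 1 count in HsMYO against 235 in SYD1, a ratio of 302 (95% interval 53.7 to 12000), and 141 in SYD2, a ratio of 141 (24.9 to 5610). The cellulase gene GH9B15 was 36.6-fold lower, LTP3 was 11.3-fold lower and the polygalacturonase gene PGAZAT was 9.07-fold lower. The meristem gene BP was lower (-0.68, adjusted p = 8.6e-06), and so was the seed coat gene MUM2 (-0.85, adjusted p = 9.7e-08). The seed coat gene PER36 was higher (2.14, adjusted p = 0.0031; 1.81 without HsMYO without ABA replicate 1, adjusted p = 0.057), and so was the endosperm marker FWA (2.62, adjusted p = 3.6e-05). As lists, seed coat markers (1 higher, 2 lower of 3, adjusted p = 0.091), endosperm markers (1 and 0 of 3, adjusted p = 0.44) and root markers (5 and 2 of 13, adjusted p = 0.091) were not called.

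Cell cycle genes were lower as a list (0 higher, 11 lower of 24, the same adjusted over the list alone; adjusted p = 1.7e-05; adjusted p = 0.42 with an estimated correlation). Ribosome genes were lower (0 and 9 of 19, or 0 and 13 adjusted over the list alone; adjusted p = 0.011; adjusted p = 0.59 with an estimated correlation), as were LEA genes (2 and 5 of 12, the same adjusted over the list alone; adjusted p = 0.033; adjusted p = 0.59 with an estimated correlation). SWI/SNF subunits, with SYD among them, were lower (0 and 3 of 13, adjusted p = 0.045), and so were shoot meristem markers (0 and 2 of 7, adjusted p = 0.044), each with an adjusted p = 0.36 with an estimated correlation. SYD, the target of the microRNAs, is among the 3 lower subunits. The list median was -0.07, and the other subunits were not tested without SYD. Photosynthesis genes were higher (11 and 1 of 31, or 14 and 1 adjusted over the list alone; adjusted p = 0.011; adjusted p = 0.6 with an estimated correlation), as were reserve mobilisation genes (7 and 0 of 17, or 8 and 0 adjusted over the list alone; adjusted p = 0.032; adjusted p = 0.59 with an estimated correlation). Gibberellin genes were higher (6 and 3 of 18, the same adjusted over the list alone; adjusted p = 0.033; adjusted p = 0.36 with an estimated correlation), and so were receptors (5 and 0 of 9, or 6 and 1 adjusted over the list alone) and cell wall loosening genes (7 and 4 of 16, or 8 and 5), both at an adjusted p of 0.035 and an adjusted p = 0.5 with an estimated correlation. The number of called lists was 6 without HsMYO without ABA replicate 1, 5 without HsMYO without ABA replicate 2 and 4 without SYD2 without ABA replicate 2.

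Setting the SYD lines against each other shows which effects were private to 1 SYD line. It cannot show that effects shared by both lines belong to SYD. GLK2, PORA and AHG1 differed between the lines, while SYD itself did not differ detectably. Of the genes called in SYD1 against HsMYO (5104 without ABA, 5139 on ABA) and SYD2 against HsMYO (5075 and 5009), 3674 were called in the same direction in both lines without ABA (2 in opposite directions) and 3647 on ABA (1 in opposite directions). Simulated draws with a shared HsMYO control and no effect of SYD gave at most 1 shared gene. With no effect almost no gene is called, so that number was low by construction. Independent lists of these sizes would share 674 genes without ABA and 660 on ABA, leaving the shared control aside. The draws gave a correlation across genes of 0.46 and 0.44 where the data gave 0.87 and 0.82. A trait of the HsMYO line itself would be shared by both comparisons as well, since there was 1 control line.

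Directly compared, the lines differed for 135 genes without ABA (81 higher in SYD1, 54 lower) and 166 on ABA (97 higher, 69 lower). SYD itself did not differ detectably (0.02, adjusted p = 0.98, and 0.13, adjusted p = 0.76). GLK2 was higher in SYD1 under both treatments (0.37, adjusted p = 0.025, and 0.36, adjusted p = 0.027), PORA was higher without ABA (1.12, adjusted p = 0.02) and AHG1 lower without ABA (-1.07, adjusted p = 0.038). On ABA the myrosinase-associated gene ESM1 was higher in SYD1 (1.62, adjusted p = 0.0018). These genes were chosen after their values were seen. The shared counts were 2011 without HsMYO without ABA replicate 1, and on ABA 2343 without SYD2 on ABA replicate 2 and 2357 without SYD1 on ABA replicate 2.

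The number called per line fell to 3065 (SYD1) and 2674 (SYD2) without HsMYO without ABA replicate 1. For SYD1 it was 3342 and 3085 without its own replicates 1 and 2 without ABA, and 3083 and 2910 without those on ABA, and for SYD2 it was 3031 and 2727 without its own replicates 1 and 2 on ABA. Between the lines, without ABA 13 and 57 genes were called without replicates 1 and 2 of SYD1 without ABA, 42 without SYD2 without ABA replicate 2, 89 without SYD1 on ABA replicate 2, and 215 and 216 without replicates 1 and 2 of HsMYO on ABA. On ABA, 53 and 51 were called without replicates 1 and 2 of SYD1 on ABA, and 99 and 36 without those of SYD2.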

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

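Of the tests below, those of cell cycle genes, of scaling, of genes switched alike in both SYD lines and of storage transcripts were chosen only after the result was seen, the bounds for cell cycle genes and shared albumin reads were made stricter after that, and the test of scaling is the last of 3 tried.

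The ABA response differed from that of HsMYO, by a test of the difference itself, for 557 genes in SYD1, 726 in SYD2 and 1008 in the mean of both. With single libraries left out these counts ran from 229 to 891, 412 to 1222 and 540 to 1584, and with no low-count filter they were 1216, 1518 and 1817. Among hormone genes these were GA3OX1 (1.44 on the log2 scale) and GA3OX2 (0.94), for gibberellin synthesis, the phosphatase genes HAI2 (-1.28) and ABI1 (-0.71), the receptor genes PYL6 (0.64) and PYL4 (0.33), the factor gene ABI3 (0.65), and the auxin genes GH3.3 (-1.62) and PIN7 (0.54). Among seed and stress genes they were ECP63 (1.37), LEA4-5 (0.89), OLEO3 (-0.66), P5CS1 (0.93), ADH1 (-1.39), HSP23.6-MITO (1.66), HSP17.6A (2.49) and STS (-4.07). Among growth genes they were TIP1;1 (2.56), EXPA1 (-0.75), the division genes CDKB2;2 (0.75) and KN (0.71), the root-hair oxidase gene RHD2 (3.64), the light-signalling gene PKS1 (4.04) and the wax gene CYP96A15 (4.54). Further genes with the largest differences were MEE26 (2.76), KUOX1 (-4.62), the cutinase gene CDEF1 (-4.19) and IOS1 (-2.93). PKS1 and RHD2 had 1 count each in HsMYO on ABA, which gives ratios for the ABA response there of 282 (95% interval 50.2 to 11200) and 431 (76.9 to 17100); CDEF1 had 0 in SYD1 on ABA, at least 1530-fold lower than without ABA. KUOX1 had 3 counts in SYD2 on ABA, a ratio for the ABA response there of 79.8 (27 to 389). Differences were also called for cell cycle (adjusted p = 3.6e-05), cell wall loosening (adjusted p = 0.031), PP2C phosphatase (adjusted p = 0.002) and heat shock genes (adjusted p = 0.031), each at adjusted p = 0.56 with an estimated correlation.

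Some of these calls rest on single libraries, and that of OLEO3 also ended with RLE scaling (-0.64, adjusted p = 0.052) and with the stricter filter (-0.64, adjusted p = 0.053). Without HsMYO on ABA replicate 1, PYL6 (0.56), OLEO3 (-0.49), HSP17.6A (2.19), GH3.3 (-1.02) and RHD2 (2.76) were not called, and without replicate 2 of that group, CDKB2;2 (0.56), KN (0.5), PIN7 (0.41), PKS1 (3.28), KUOX1 (-3.59) and CDEF1 (-3.58) were not. Without HsMYO without ABA replicate 1, the call ended for PYL4 (0.35), LEA4-5 (0.55), OLEO3 (-0.69), KN (0.79), HSP23.6-MITO (1.6), HSP17.6A (1.51), PIN7 (0.53) and MEE26 (3.01), and ECP63 was at 0.8. Without replicate 2 of that group it ended for PYL6 (0.51), PYL4 (0.32), OLEO3 (-0.61), CDKB2;2 (0.65), KN (0.63), PIN7 (0.55) and MEE26 (2.44). Leaving out SYD1 on ABA replicate 1 ended it for PYL4 (0.37), CDKB2;2 (0.77), KN (0.66) and GH3.3 (-1.54), and leaving out replicate 2 for PYL4 (0.33) and OLEO3 (-0.58). Leaving out SYD1 without ABA replicate 1 ended it for PYL4 (0.3), OLEO3 (-0.69), CDKB2;2 (0.75), KN (0.72) and MEE26 (2.68), and leaving out replicate 2 for OLEO3 (-0.61), CDKB2;2 (0.76), KN (0.7) and HSP17.6A (2.38). Leaving out SYD2 on ABA replicate 1 ended it for PYL4 (0.35), CDKB2;2 (0.68), KN (0.66), HSP17.6A (2.38) and PIN7 (0.5), and leaving out replicate 2 for PYL4 (0.32) and OLEO3 (-0.6). Leaving out SYD2 without ABA replicate 1 ended it for OLEO3 (-0.66), and leaving out replicate 2 for OLEO3 (-0.6) and KN (0.66). PKS1 was at 6.09 without HsMYO on ABA replicate 1 and RHD2 at 5.69 without replicate 2.

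Without ABA, EXPA8, GLK2 and GA20OX2 were higher and LEA4-5 and ECP63 lower in the SYD lines, the direction of seeds further along germination. Seed storage genes, which ABA raised in HsMYO, went the other way (6 higher, 0 lower of 14, list not called). If stage were the main cause, genes changed in a SYD line would mostly go opposite to ABA; 60.7% of 2927 such genes did in SYD1 (ABA response taken from SYD2) and 51.7% of 3009 in SYD2 (ABA response taken from SYD1), shares that neither reach the 75% set for it nor both stay within the 60% set against it. Cell cycle genes, which ABA lowered in HsMYO, were lower in the SYD lines (11 lower, 0 higher), which goes against a later stage for them but leaves it open, since both list calls end (adjusted p = 0.61 for ABA in HsMYO and adjusted p = 0.42 without ABA, with an estimated correlation). A scaling error would shift every gene alike. Under any common factor on the HsMYO libraries, from 4-fold down to 4-fold up, the called genes stayed at 100% of 6311 or more. TMM scaling had already centred the genes (median log2 0.011), so a further factor was bound to add calls, and this test cannot decide. A later stage, an effect of SYD and a trait of the single HsMYO line cannot be told apart here.

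In 29 genes, chosen after their values were seen, the SYD lines differed from HsMYO at least 8-fold in the same direction in both treatments (15 higher, 14 lower), among them LTP3, UMAMIT28 and the non-coding gene AT2G01422 (lower) and ARD3, PR1 and BAM5 (higher). Linked differences between the lines would put these genes close together, and 2 pairs lay within 200 kb, where random sets of tested genes had a median of 1 and a 95th percentile of 4 (permutation p = 0.47). The 29 were 69% of the genes so changed in SYD1 and 78.4% of those in SYD2, so most were not private to 1 SYD line. A fixed difference in the HsMYO line and a steady effect of SYD may each give this pattern, and with 1 control line they cannot be told apart.

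Transcripts of the 2S albumin genes were higher in the SYD lines, with summed counts of SESA1 to SESA5 of 68.1 CPM in HsMYO, 259 in SYD1 and 189 in SYD2 without ABA, and 86.8, 525 and 280 on ABA. The lowest SYD line library had 2.71-fold the sum of the highest HsMYO library on ABA and 1.47-fold without ABA, where libraries lay far apart (96.2 and 40 CPM in HsMYO, 362 and 156 in SYD1, 141 and 237 in SYD2). Reads shared among the near-identical copies stay open in both treatments, because the rule for counting such reads is not known and some rules would change the sum. More RNA left from the dry seed would raise LEA and oleosin transcripts too, but the LEA list had a median of -0.47 without ABA and -0.28 on ABA, and the 4 oleosin genes -0.1 and -0.68. ABA itself raised LEA genes (median 4.24 in HsMYO) and the oleosin genes OLEO2 (5.53) and OLEO3 (3.3). These levels therefore do not reflect leftover RNA alone, and that explanation stays open. An effect of SYD on albumin genes and a trait of the HsMYO line remain open too.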

How the results depend on the processing

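All alternatives were planned, and no test in this part was chosen after a result was seen. Over the named genes, 3286 of 3441 values under the alternatives kept direction and side of the threshold, 130 lost the call, 15 gained one and 10 changed sign. The sign changes were in values that were not called: ABI4 without ABA (-0.02 with no low-count filter, -0.01 with the stricter filter, -0.01 with only the groups compared, -0.1 to 0.11 with single libraries left out, the lowest without HsMYO without ABA replicate 2, and also -0.01 without SYD1 on ABA replicate 1 and -0.04 without SYD2 without ABA replicate 1), RAB18 on ABA (-0.59 to 0.05 with single libraries left out, the highest without HsMYO on ABA replicate 1), RAB18 without ABA (-0.23 to 1.49, the lowest without HsMYO without ABA replicate 2), and the response differences of EM1 (-0.22 to 1.11) and RD29B (-0.17 to 0.71), both lowest without HsMYO without ABA replicate 1. RLE scaling and DESeq2 left every total of called genes within 1.5 times, but with DESeq2 the genes lower on ABA went from 3111 to 1729 in the mean of the SYD lines, from 2384 to 1363 in SYD1 and from 2298 to 1113 in SYD2. Those lower in SYD2 without ABA went from 2218 to 1421. RLE scaling alone moved the mean of the SYD lines on ABA the same way, to 3682 higher and 2689 lower. It moved the mean response difference to 601 higher and 442 lower. With DESeq2 the calls, among others, for XTH13 without ABA and for RHD2, PKS1 and HSP23.6-MITO in the response difference ended (adjusted p = 0.18, 0.1, 0.059 and 0.066), as did those for RD29B without ABA (adjusted p = 0.13) and EM1 on ABA (adjusted p = 0.16). With no low-count filter the response difference called 1216 (SYD1), 1518 (SYD2) and 1817 genes (mean) and 2 lists, and SYD1 against SYD2 called 616 genes without ABA and 471 on ABA. With replicate number as a block these response differences called 912, 1254 and 1628 genes, and SYD1 against SYD2 without ABA 308. With only the groups compared, SYD1 against SYD2 on ABA called 410. Beyond the part that RLE scaling shows, the cause of these shifts was not tested. A required 2-fold change, a stricter definition, left 2977, 2767 and 2416 genes for ABA in HsMYO, SYD1 and SYD2. For SYD1, SYD2 and their mean it left 1247, 1052 and 1199 without ABA, 1162, 1111 and 1216 on ABA, and 229, 268 and 290 in the response difference. It left 49 and 76 between the SYD lines and 787 and 771 shared by them, and the size differences over these genes were 0.031 (SYD1 minus HsMYO, a change of sign), -0.155 (SYD2 minus HsMYO) and -0.156 (SYD2 minus SYD1). At an adjusted p under 0.01 the counts were 3000, 2819 and 3872 without ABA, 2927, 2661 and 3836 on ABA, 228, 308 and 443 in the response difference, 32 and 68 between the SYD lines, and 2083 and 1997 shared. An estimated correlation left 4 called lists for ABA in HsMYO, 4 in SYD1, 5 in SYD2, and 0 for the SYD lines without ABA, 0 on ABA and 0 in the response difference. Leaving out single libraries gave ranges of 8463 to 10719 genes for ABA in HsMYO, 7036 to 9831 in SYD1 and 6215 to 9053 in SYD2. Without ABA they were 3065 to 5858 (SYD1), 2674 to 5791 (SYD2) and 3455 to 7016 (mean), and on ABA 2910 to 5312, 2727 to 5223 and 4737 to 6573. The response difference ranged over 229 to 891, 412 to 1222 and 540 to 1584, SYD1 against SYD2 over 13 to 216 without ABA and 36 to 217 on ABA, and shared genes over 2011 to 4254 and 2343 to 3798. The lowest counts came without HsMYO without ABA replicate 1 in all 3 comparisons without ABA, for shared genes there and for the mean response difference. Size differences ranged over -0.035 to -0.002, -0.099 to -0.047 and -0.079 to -0.021, and SYD itself over -0.84 to -0.78 without ABA and -0.69 to -0.46 on ABA. Called lists ranged over 7 to 9 (ABA in HsMYO), 8 to 9 (SYD1), 7 to 7 (SYD2), 4 to 11 (SYD lines without ABA), 4 to 7 (on ABA) and 2 to 7 (response difference). Depth limits the genes with few counts on ABA, such as EXT10 and COBL9, whose changes are bounds or wide intervals.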

Other observations

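The hypothesis of a smaller ABA response in the SYD lines was tested as planned, and the gene families below were chosen after the data were seen, by the letters of their symbols.

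Reduced SYD might weaken the ABA response as a whole rather than in particular genes. Of genes whose response differed in SYD1 and that ABA changed in SYD2, 53.9% (233 of 432) differed in the direction opposite to ABA, and with the lines exchanged 73.7% (427 of 579) did. The prediction of a smaller response was at least 75% for both choices of lines and that against it at most 60% for both, so these values decide neither.

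Families of at least 10 tested genes were compared with all other genes, 123 in all. Called were 7 for ABA in HsMYO, 5 in the response difference, 8 in the SYD lines on ABA and 2 without ABA, and 0 in any of these with an estimated correlation, for which the adjusted p is given second; some of them follow. On ABA, HsMYO had lower KCS genes for the elongation of wax and suberin fatty acids (0 higher, 13 lower of 16, median -1.38, adjusted p = 2.4e-11, 0.66), FLA arabinogalactan genes (0 and 9 of 14, -1.06, adjusted p = 1.2e-06, 0.71), XTH wall-remodelling genes (2 and 15 of 24, -1.24, adjusted p = 0.00058, 0.72) and IRX secondary wall genes (0 and 7 of 10, -2.37, adjusted p = 0.013, 0.71). The SYD lines on ABA had higher FLA genes (9 and 1 of 14, 0.47, adjusted p = 0.0064, 0.82) and UGT glycosyltransferase genes (21 and 6 of 42, 0.3, adjusted p = 0.033, 0.82). NAC transcription factor genes, many of which act in stress and ageing, were lower in the SYD lines on ABA (7 and 17 of 53, -0.17, adjusted p = 0.01, 0.82) and without it (6 and 22 of 53, -0.27, adjusted p = 0.0037, 0.81). KCS genes (3 and 0 of 16, 0.26, adjusted p = 0.012, 0.9) and FLA genes (3 and 0 of 14, 0.25, adjusted p = 0.049, 0.9) fell less on ABA in the SYD lines.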
